A study of Dictyostelium discoideum with 12 samples.

How the data were processed

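Polyadenylated RNA from growing Dictyostelium discoideum cells was measured in 12 libraries, 3 each from wild-type cells (strain AX2), a CbfA mutant (strain JH.D), and this mutant expressing the CbfA carboxy-terminal domain of D. discoideum (DdCTD) or of Polysphondylium pallidum (PpCTD). Cells were cultured in HL-5 broth and kept frozen as dry pellets, per the labels' protocols. Libraries came from the TruSeq RNA kit v2, per the labels' protocols, which does not mark strand, so reads from overlapping or antisense genes could not be told apart. CASAVA 1.8 was used, per the submitters' processing notes. The aligner, the genome build, the annotation and the counting program are not given in the sources used here.

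The authors deposited RPKM values for 12317 gene models in each library. The unit was settled from the values. With 1 constant per library, a model length could be found for all 12317 models at which the values of the 12 libraries lay at most 0.000169 from whole numbers, once 1 read was taken as having been added to every model, so that no RPKM value lay under that of 1 read. The lengths were searched for, at first up to slightly above the annotated length, or up to 49999 nucleotides for models without one. This settled 12204 models, and the other 113 were then searched up to 49999 nucleotides. The same search within the annotated length gave whole numbers for 0 of 300 models whose values had been shuffled between models. This gave the reads behind each value. The recovered reads came to 17164778 to 54082760 per library. In a model of 1 kilobase, 1 read corresponded to 0.0185 to 0.0583 RPKM, and a count of 0 allowed up to 3 reads, or 0.055 to 0.175 RPKM from the deepest to the shallowest library. These floors cover counting error only. Between 10.5% and 16.5% of the models had 0 reads in a library, and 924 had 0 reads in all 12. Among these were both members of 83 of the 87 pairs of models listed as copies of each other, all 83 on chromosome 2; no value could be reported for these genes.

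Gene symbols and the order of genes along chromosomes came from a RefSeq gene table of the assembly dicty_2.7, which matched 12160 models; 157 had no match, and 3623 had a descriptive symbol. The annotated lengths used in the search above came from the same table. Its coordinates were not used otherwise, since the build behind the deposited values is not known.

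Fold changes and tests were computed on log2(RPKM + 1) with limma 3.58.1 (R 4.3.3), with an intensity trend, without robust estimation, with 1 coefficient per group and all 12 libraries in 1 model. The pseudocount of 1 makes fold changes of genes with low values smaller than the ratio of their RPKM values. The 8859 models with a mean RPKM of at least 1 over the 12 libraries were tested and 3458 were not. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The plan written before the data were examined named a test for read counts, with limma on log2 values as the branch for normalized values; the second branch was followed because the deposited values are RPKM. The same plan set the comparisons, the gene lists, the rule for naming genes and most of the alternatives before the data were examined. Recovery and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

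The 6 comparisons were mutant with wild type, each domain library group with the mutant, each with wild type, and the PpCTD with the DdCTD group. Genes reversed by a domain were those called in mutant against wild type and called in the opposite direction in domain against mutant. These counts share the mutant libraries, as does the overlap of the responses to both domains, so the counts given by noise alone were simulated in 50 draws of unchanged groups. The controls of 3 libraries could not be divided into parts of at least 2, so no split of the mutant libraries was possible.

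The fit was tested on simulated data for mutant against wild type, with 200 of the genes changed by known folds and 8444 genes tested. Of 99 tested genes changed 2-fold, 84 (84.8%) were called; of 99 changed 4-fold, 99 (100%) were called; 9 unchanged genes were called. The simulated changes went up and down in equal number and touched few genes. The 9 false calls therefore say nothing about false calls from scaling or composition in the real comparisons, which called far more genes.

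There were 22 gene lists, chosen by symbol: cAMP signalling and early aggregation, prestarvation and quorum factors, prestalk and prespore markers, RNA interference and chromatin silencing, retroelement genes, cysteine and aspartic proteases and lysosomal enzymes, vacuolar ATPase, cytosolic ribosomal proteins, proteasome, polyketide synthases, cytochrome P450, ABC transporters, the actin family, cytoskeleton and cell adhesion, Ras, Rap and Rac GTPases, heat shock proteins and chaperones, oxidative stress and detoxification, DNA replication and cell cycle, transcription factors, the tiger (tgr) family, the hssA/2C/7E family and autophagy. Symbol patterns were matched without regard to case, a choice made after the data were seen because the cytochrome P450 symbols are in capitals; it also placed hspc300, a SCAR complex gene, in the heat shock list. Lists with tested members, 20 of the 22, were tested with camera in limma with a preset correlation of 0.01, adjusted over lists within a comparison, beside camera with an estimated correlation and fry. Camera compares a list with the other genes; fry tests whether the members of a list move, on balance, one way, and compares the list with nothing.

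Genes were named by rule. cbfA came first in every library. Per comparison followed the 10 largest rises and 10 largest falls (5 and 5 for the comparisons with wild type after domain expression and between domains) among genes with an adjusted p under 0.05, a mean of at least 1, every library of one group above every library of the other, and a descriptive symbol. Up to 2 bare identifiers per direction and up to 4 members of each list with the smallest p were added, and acaA, agnC and retroelement genes whatever their values. Not all genes allowed by the rule are printed. Complete separation of 3 libraries from 3 arises by chance in 10% of genes. Members of multicopy families such as actin are uncertain between copies.

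Alternatives were quantile normalization, a pseudocount of 0.1, no filter on low values, the replicate number as a block, only the libraries compared, a threshold of a doubling or halving, and leaving out each library in turn. Added after the data were seen were limma voom on the recovered reads with median-ratio scaling, and all counts without a run of genes on chromosome 2. No library was left out of the main comparisons.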

Results

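Messenger RNA levels of growing Dictyostelium discoideum amoebae were measured in 4 groups of 3 libraries: wild-type cells, a CbfA mutant, the mutant with the carboxy-terminal domain of its own species' CbfA (DdCTD), and the mutant with the corresponding domain of Polysphondylium pallidum (PpCTD). CbfA is the C-module-binding factor, a DNA-binding regulator known from work on the retrotransposon TRE5-A. The reads behind the deposited RPKM values came to 42786566, 20615700 and 17164778 for wild type, 23245795, 22050206 and 21760078 for the mutant, 23741200, 23168688 and 20580167 for DdCTD, and 19761134, 20443365 and 54082760 for PpCTD. The 10 most abundant genes took 9.26% to 9.73% of the reads in mutant libraries, 7.78% to 8.9% in wild type, 6.97% to 7.65% with PpCTD and 6.39% to 6.83% with DdCTD. Across genes, which are not independent replicates, Pearson's r was 0.974 to 0.997 between libraries of 1 group and 0.856 to 0.984 between groups. Nothing in the labels says that the replicates came from separate cultures, so the p-values below measure only the spread between these libraries. Expression values are mean RPKM ± SD (n = 3 libraries per group), fold changes are differences of log2(RPKM + 1) from limma, and these understate the ratios of genes with low values.

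The gene cbfA itself was read at 36.6, 37.9 and 38.0 RPKM in the wild-type libraries, 86.2, 80.6 and 75.3 in the mutant, 222.8, 237.2 and 208.6 with DdCTD, and 25.8, 31.6 and 26.3 with PpCTD. Whether reads of an expressed domain count on this gene was not tested, and the labels do not say how the gene was altered in the mutant, so its level did not check the mutant label. The mutant level was 2.15-fold that of wild type (limma log2 change 1.08, adjusted p = 3.3e-06), and the PpCTD level lay below wild type (-0.42, adjusted p = 0.00534). The Argonaute gene agnC, named in earlier work on CbfA, stood at 0.0609 ± 0.00819 RPKM in wild type and 13.8 ± 1.79 in the mutant, with 14 and 3355 reads. It fell to 0.424 ± 0.224 with DdCTD and 0.535 ± 0.277 with PpCTD. It stayed above wild type by 0.41 (limma adjusted p = 0.044) and 0.52 (adjusted p = 0.0231), calls that were lost without DdCTD replicate 1 (0.29, adjusted p = 0.167), without PpCTD replicate 1 (0.39, adjusted p = 0.0763), or after quantile normalization (0.05 and 0.16). The adenylyl cyclase gene acaA, also named in earlier work, lay at 0.383 to 1.97 RPKM in single libraries, and its mean under 1 kept it from being tested. None of the 12317 gene models carried a retroelement symbol, so retroelement genes could not be reported.

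**Figure D1:**
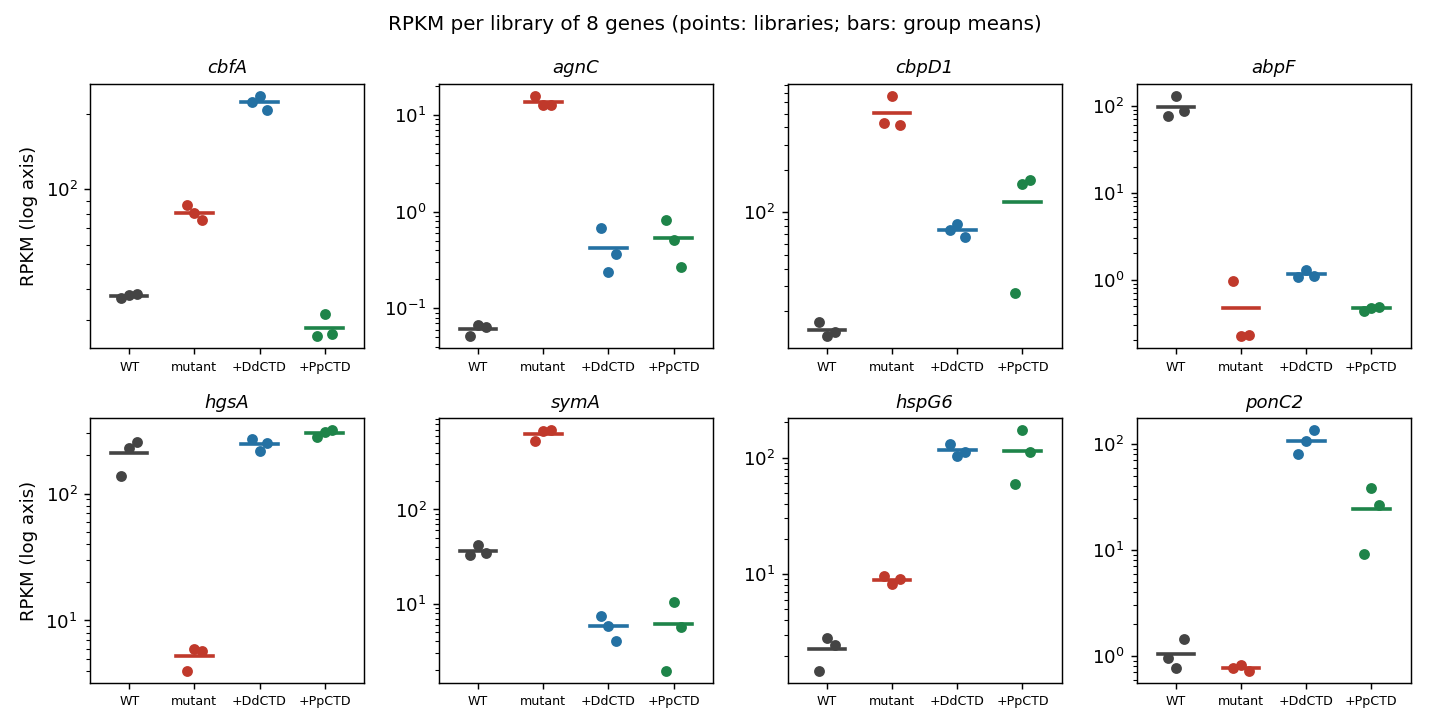
RPKM (log axis) of 8 genes in each of the 12 libraries, with group means as bars: wild type (WT), mutant, mutant with DdCTD and mutant with PpCTD. agnC, cbpD1 and symA were highest in the mutant libraries, hgsA was lowest there, abpF was high in wild type alone, and hspG6 and ponC2 were highest with a domain.

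The first comparison asked how gene expression in growing mutant cells differs from wild type. Among the genes that rose, the calcium-binding protein gene cbpD1 went from 14.7 ± 1.71 RPKM to 507 ± 142 (SD, n = 3), symA from 36.8 ± 4.97 to 633 ± 84.6, and the ABC transporter gene abcG21 from 10.96 ± 1.95 to 196 ± 34.5. The oxysterol-binding protein gene osbA rose from 0.796 ± 0.261 to 43.4 ± 16.5, gppA from 0.446 ± 0.0469 to 25.7 ± 0.144, and dia2 from 3.78 ± 0.892 to 77.5 ± 34.6. Some of these genes were almost silent in wild type: rdiB had 0 reads there and 801 in the mutant, the cytochrome P450 gene CYP513F1 had 2 and 1585, psiQ had 12 and 2807, and DDB_G0283511 had 4 and 2708. DDB_G0267726 rose from 26.3 ± 5.45 to 2333 ± 59.0.

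Among the genes that fell, the actin-binding protein gene abpF dropped from 97.6 ± 29.3 RPKM to 0.476 ± 0.428 (SD, n = 3), hgsA from 207 ± 62.7 to 5.23 ± 1.07, the calcium-binding protein gene CBP2 from 287 ± 33.9 to 10.03 ± 3.64, and wipA from 135 ± 64.8 to 6.64 ± 2.76. The alternative oxidase gene aoxA fell from 50.6 ± 39.5 to 3.23 ± 1.09, gdcA from 33.0 ± 10.7 to 2.80 ± 1.17, psiF from 46.4 ± 18.6 to 2.64 ± 1.22, cafA from 61.6 ± 23.8 to 5.21 ± 0.281, and ctbsB from 30.4 ± 12.03 to 2.19 ± 0.279. DDB_G0282815 fell from 5130.0 ± 247 to 57.4 ± 13.2. thfA (107 ± 3.73 to 8.15 ± 0.340) and DDB_G0277333 (162 ± 37.1 to 3.30 ± 0.637) also fell, and both lie in a run of genes at the end of chromosome 2 that were lower as a block. Of the 8859 genes tested, limma called 4844 (54.7%), of which 2292 rose and 2552 fell, and 1480 changed at least 2-fold. The 10 rises and 10 falls with descriptive symbols had adjusted p from 1.24e-09 (thfA) to 0.000436 (cafA).

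Actin family genes were lower in the mutant: act2 fell from 24.5 ± 5.34 RPKM to 2.72 ± 0.768 and act12 from 14.1 ± 1.49 to 2.37 ± 0.661 (SD, n = 3), although near-identical actin genes are uncertain between copies. Of 30 tested members 20 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -1.05 relative to all genes; camera gave an adjusted p of 6.24e-05, and an adjusted p = 0.827 with an estimated correlation. Proteasome subunit genes were lower too, psmE3 falling from 34.7 ± 4.15 to 13.6 ± 1.57 and psmC6 from 148 ± 13.5 to 71.5 ± 8.33. Of 38 members 30 fell and 1 rose, the same numbers when adjusted over the list alone, with a relative median of -0.55 (camera adjusted p = 4.63e-06; adjusted p = 0.827 with an estimated correlation). Ribosomal protein genes were higher, rps3 rising from 4263 ± 223 to 7891 ± 476 and rpl3 from 4168 ± 253 to 7142 ± 387, while rps3a, which lies in the chromosome 2 run, fell. Of 76 members 44 rose and 8 fell (47 and 10 adjusted over the list alone), with a relative median of 0.29 (camera adjusted p = 6.24e-05; adjusted p = 0.827 with an estimated correlation). After quantile normalization 31 rose and 17 fell, this relative median was 0.06 and the call was lost. With median-ratio scaling it was 0.30, where 36 rose and 8 fell. Quantile normalization gives every library the same set of values, so it can remove a joint shift of genes this abundant. Here and below, the loss of a ribosomal protein call with it therefore does not decide whether these genes moved. Transcription factor genes rose in 33 and fell in 13 of 70 cases, unchanged when adjusted over the list alone, with a relative median of 0.26 (camera adjusted p = 0.0142; adjusted p = 0.827 with an estimated correlation). gtaE rose from 0.904 ± 0.3997 to 18.9 ± 2.90. The serum response factor gene srfA rose from 0.138 ± 0.0399 to 5.39 ± 0.877 and bzpN from 4.70 ± 0.315 to 22.0 ± 2.31.

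Other members moved in lists that camera did not call. The developmental marker genes ecmA (0.0394 ± 0.0154 to 3.44 ± 0.902 RPKM), cudA (1.60 ± 0.762 to 16.9 ± 2.65) and tagC (1.93 ± 0.228 to 8.38 ± 0.701) rose in the mutant (SD, n = 3). Of 14 prestalk and prespore markers 8 rose and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.056). The superoxide dismutase gene sodA fell from 1134 ± 62.8 to 210.4 ± 29.7, the thymidylate synthase gene thyA from 21.2 ± 3.03 to 3.16 ± 0.820, and pcna from 55.9 ± 19.7 to 10.5 ± 3.37. The cyclic nucleotide phosphodiesterase gene pdsA rose from 326 ± 18.4 to 590.0 ± 48.4. Of 29 DNA replication and cell cycle genes 14 fell and 4 rose (camera adjusted p = 0.186).

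The next comparison set the mutant with the D. discoideum domain against the mutant. No library with a construct and no domain was analysed. Differences of either domain group from the mutant therefore cannot be told apart from effects of carrying a construct or its selection. With DdCTD, symA dropped from 633 ± 84.6 RPKM to 5.78 ± 1.65, abcG21 from 196 ± 34.5 to 4.51 ± 0.755, sigI from 1030.0 ± 51.5 to 104 ± 51.6, and omt4 from 52.5 ± 15.9 to 4.68 ± 0.833 (SD, n = 3). rdiB, psiQ, CYP513F1 and agnC, which had risen in the mutant, had log2 changes of -3.84, -3.70, -3.54 and -3.38. cmbB fell from 248 ± 27.9 to 20.4 ± 12.2, and cxgS from 1057 ± 44.9 to 80.5 ± 106, with a spread above its mean. In the other direction, thyA rose from 3.16 ± 0.820 to 259.5 ± 74.3, gdcA from 2.80 ± 1.17 to 201 ± 38.4, CBP2 from 10.03 ± 3.64 to 492 ± 67.1, and aoxA from 3.23 ± 1.09 to 175 ± 28.4. The ponticulin-like genes ponB and ponC1 to ponC5 rose by 5.39 to 5.90, ponC2 from 0.772 ± 0.0464 to 107 ± 27.1, with reads uncertain between copies. DDB_G0289411 and DDB_G0280201 rose by 8.20 and 7.43, and DDB_G0268332 and DDB_G0267728 fell (-6.10 and -5.88). Limma called 5757 genes (65.0%), 4084 up and 1673 down, or 70.9% up; the share was 43.3% after quantile normalization and 50.2% with median-ratio scaling of the reads. These scalings moved the median of all genes, 0.27 as deposited, by -0.38 and -0.28, so list medians are given relative to all genes. The largest adjusted p among the 20 genes with descriptive symbols chosen by size was 0.000119 (cxgS).

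Genes for DNA replication rose with DdCTD: pcna went from 10.5 ± 3.37 RPKM to 225 ± 33.3, cdc45 from 1.98 ± 0.264 to 18.7 ± 3.50, and mcm7 from 3.42 ± 0.484 to 23.1 ± 2.23 (SD, n = 3). Of 29 members 25 rose and 2 fell (26 and 2 adjusted over the list alone), with a median of 1.12 relative to all genes (camera adjusted p = 0.00135; adjusted p = 0.923 with an estimated correlation). Small heat shock genes rose, hspG9 from 2.34 ± 0.631 to 79.9 ± 20.2 and hspG8 from 1.49 ± 0.468 to 36.2 ± 8.85, beside hspD (575 ± 37.7 to 1659 ± 107). Of 26 heat shock and chaperone genes 21 rose and 2 fell, as they did adjusted over the list alone, with a relative median of 2.11 (camera adjusted p = 0.0024; adjusted p = 0.923 with an estimated correlation). Actin genes rose in 24 and fell in 4 of 30 cases, also when adjusted over the list alone, with a relative median of 1.22 (camera adjusted p = 0.0024; adjusted p = 0.923 with an estimated correlation). Proteasome genes rose in 34 and fell in 1 of 38 cases, also when adjusted over the list alone, with a relative median of 0.60 (camera adjusted p = 0.000159; adjusted p = 0.923 with an estimated correlation). psmE3 rose by 1.83 and psmC6 by 1.30.

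Vacuolar ATPase genes were lower with DdCTD, vatC at 446 ± 30.8 RPKM against 776 ± 79.6 in the mutant and vatE at 1383 ± 71.5 against 2020.0 ± 246 (SD, n = 3). Of 8 members 7 fell and 0 rose, also when adjusted over the list alone, with a median of -0.84 relative to all genes (camera adjusted p = 0.00063; adjusted p = 0.923 with an estimated correlation; 0.0618 after quantile normalization, with a relative median of -0.58). Prestalk and prespore markers fell in 7 and rose in 1 of 14 cases, also when adjusted over the list alone, with a relative median of -0.71 (camera adjusted p = 0.00149; adjusted p = 0.553 with an estimated correlation). Among them ampA fell from 190.0 ± 17.8 to 62.7 ± 8.52 and tagC from 8.38 ± 0.701 to 2.66 ± 0.222. Ribosomal protein genes fell in 63 and rose in 0 of 76 cases (64 and 0 adjusted over the list alone), rpl28 going from 3777 ± 269 to 1890.0 ± 86.5. Their relative median was -0.72 (camera adjusted p = 1.3e-22; adjusted p = 0.676 with an estimated correlation) but 0.05 after quantile normalization, where 28 fell and 15 rose, the direction of the relative median flipped and the call was lost. Before the all-gene median was subtracted, the list median there was -0.05. With median-ratio scaling that median was -0.76, where 72 fell and 0 rose. Elsewhere the Argonaute genes agnB (15.2 ± 1.30 to 108 ± 1.73) and agnA (20.1 ± 1.99 to 44.8 ± 0.686) rose, as did the vinculin-like gene vinA (0.657 ± 0.274 to 17.3 ± 0.930), the protease gene cprA (2.43 ± 0.793 to 44.99 ± 2.81), abcG12 (9.67 ± 2.22 to 244 ± 40.8) and sodA (210.4 ± 29.7 to 1164 ± 142).

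Of the 4844 genes changed in the mutant, 3401 (70.2%) moved back with DdCTD. hgsA, CBP2 and aoxA were among the 2183 that had fallen and then rose (85.5% of the genes that fell), and symA and agnC among the 1218 that had risen and then fell (53.1% of the genes that rose). This split depended on the scaling: 1682 rose back and 2129 fell back after quantile normalization, and 1814 and 1796 with median-ratio scaling of the reads. After moving back, 1734 of these genes had no call against wild type, 1207 had passed beyond wild type, as symA did, and 460 stayed on the side of the mutant. These classes rest on calls against wild type with the deposited scaling and were not counted under the others. Of the 3961 rises above wild type, 2232 were lost after quantile normalization and 1982 with median-ratio scaling. abpF rose by 0.58 to 1.15 ± 0.120 RPKM and remained far below wild type. Independent lists of these sizes would share 1176 and 433 genes. With domain groups unchanged from the mutant, 50 simulations gave a mean of 0.04 reversed genes, at most 1. Unchanged groups leave few genes to call against the mutant. These draws therefore do not show how many of the 3401 genes come from sharing the mutant libraries. Across genes, the fold changes of mutant minus wild type and DdCTD minus mutant had r = -0.731 and a covariance of -0.738, against -0.102 and -0.017 in the simulations. The mutant libraries enter both comparisons and were not split between them, so part of the excess over independent lists can come from that sharing. The simulated covariance measures what sharing adds through the spread between these libraries, and it was small beside the observed one. A deviation common to all the mutant libraries is not in it.

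**Figure D2:**
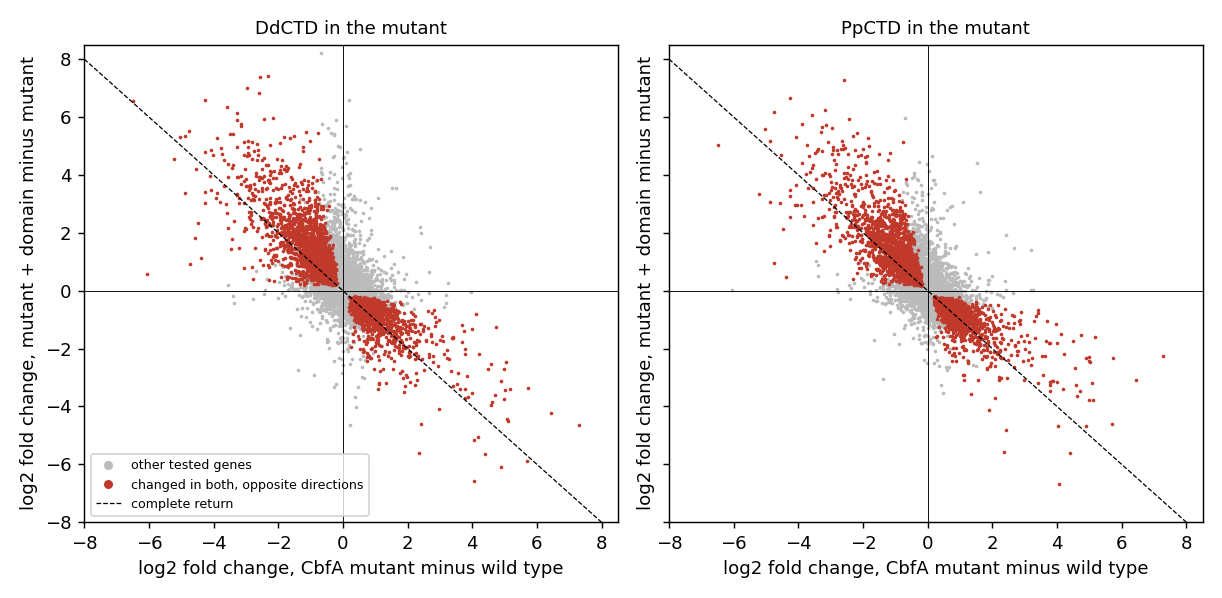
Log2 fold change of each tested gene in the mutant (mutant minus wild type, horizontal) against its change with a domain (domain minus mutant, vertical), for DdCTD on the left and PpCTD on the right. Red points are the 3401 and 3575 genes called in both comparisons in opposite directions, and the dashed line marks a complete return to the wild-type level.

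The mutant with the P. pallidum domain was compared with the mutant in the same way and with the same limit. The question was whether the same genes moved with a domain from another species. gdcA rose from 2.80 ± 1.17 RPKM to 303 ± 143, CBP2 from 10.03 ± 3.64 to 809.8 ± 315, thyA from 3.16 ± 0.820 to 252 ± 63.4, and hgsA from 5.23 ± 1.07 to 299 ± 19.6 (SD, n = 3). The cytochrome P450 gene CYP519E1 rose from 0.589 ± 0.0791 to 50.5 ± 13.1, the GMP synthase gene guaA from 11.6 ± 0.480 to 371 ± 69.3, cbpE from 3.88 ± 0.751 to 159 ± 80.0, and cafA from 5.21 ± 0.281 to 222 ± 146. aoxA and ponB rose by 4.88 and 4.75. symA fell from 633 ± 84.6 to 6.06 ± 4.28, abcG21 from 196 ± 34.5 to 7.75 ± 5.85, omt4 from 52.5 ± 15.9 to 3.34 ± 0.609, and osbK from 427 ± 221 to 46.6 ± 16.6. rdiB, psiQ, agnC, CYP513F1, sigI and osbA had log2 changes of -3.63, -3.48, -3.27, -3.14, -2.90 and -2.67. DDB_G0284549 and DDB_G0282559 rose by 7.28 and 6.64, and DDB_G0283465 and DDB_G0278127 fell (-5.61 and -5.57). Limma called 5449 genes (61.5%), 3475 up and 1974 down, or 63.8% up, against 42.6% after quantile normalization and 49.7% with median-ratio scaling. These moved the all-gene median of 0.16 by -0.27 and -0.17. Adjusted p of the 20 genes with descriptive symbols reached at most 9.38e-05 (sigI).

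DNA replication genes rose with PpCTD as well, pcna to 207 ± 46.3 RPKM and cdc45 to 18.0 ± 4.90 (SD, n = 3), 25 up and 2 down of 29, also when adjusted over the list alone (relative median 1.24; camera adjusted p = 0.000246; adjusted p = 0.623 with an estimated correlation). Heat shock and chaperone genes numbered 21 up and 2 down of 26, also when adjusted over the list alone (relative median 2.42; camera adjusted p = 0.000347; adjusted p = 0.623 with an estimated correlation), with hspG9 at 74.4 ± 37.9. Actin genes numbered 24 up and 1 down of 30 (24 and 2 adjusted over the list alone; relative median 1.37; camera adjusted p = 0.000263; adjusted p = 0.623 with an estimated correlation). Proteasome genes numbered 35 up and 1 down of 38, also when adjusted over the list alone (relative median 0.80; camera adjusted p = 9.18e-07; adjusted p = 0.623 with an estimated correlation). Vacuolar ATPase genes fell in 7 of 8 cases, also when adjusted over the list alone, vatF going from 788 ± 75.6 to 487 ± 36.7 (relative median -0.74; camera adjusted p = 0.00195; adjusted p = 0.623 with an estimated correlation). Prestalk and prespore markers fell in 7 and rose in 1 of 14 cases, also when adjusted over the list alone (relative median -0.55; camera adjusted p = 0.0103; adjusted p = 0.623 with an estimated correlation). Transcription factor genes, with srfA falling from 5.39 ± 0.877 to 0.788 ± 0.246 and dimA from 41.7 ± 2.98 to 15.7 ± 1.01, fell in 29 and rose in 16 of 70 cases, also when adjusted over the list alone (46 and 9 after quantile normalization, 44 and 10 with median-ratio scaling; relative median -0.38; camera adjusted p = 0.00267; adjusted p = 0.623 with an estimated correlation). Ribosomal protein genes fell in 57 and rose in 2 of 76 cases (58 and 3 adjusted over the list alone; camera adjusted p = 1.11e-13; adjusted p = 0.623 with an estimated correlation). Their relative median of -0.53 flipped to 0.04 after quantile normalization, where 25 fell and 13 rose, and the call was lost. With median-ratio scaling that median was -0.55, where 65 fell and 0 rose.

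With PpCTD, 3575 (73.8%) of the 4844 mutant-changed genes moved back: 2124 that had fallen (83.2%), hgsA and CBP2 among them, and 1451 that had risen (63.3%), such as osbA and symA. Here too the split was 1708 and 2175 after quantile normalization and 1887 and 1871 with median-ratio scaling. Of the 3575 genes, 2222 had no call against wild type, 938 had passed beyond it and 415 stayed on the mutant side. These classes were not counted under the other scalings, which lost 1181 and 882 of the 2652 rises above wild type. Independent lists would share 1001 and 511 genes. The simulations of unchanged domain groups, with the limit given for DdCTD, gave a mean of 0.06, at most 1. Across genes r was -0.768 and the covariance -0.726, against -0.099 and -0.016 in simulations. In both domain groups 3212 genes (66.3%) moved back. Genes of any kind that moved the same way in both groups against the mutant numbered 4816, 3305 up and 1511 down (2225 and 2960 after quantile normalization, 2500 and 2461 with median-ratio scaling). Independent lists would share 1602 and 373. Simulations of unchanged domain groups gave a mean of 0.02, which does not show how many of these genes come from sharing the mutant libraries. Carrying a construct or its selection cannot be told apart from a shared action of the domains. The fold changes for the domains had r = 0.950 and a covariance of 1.13 across genes, against 0.497 and 0.016 in simulations with shared mutant libraries. The simulated covariance was again small beside the observed one, with the limit given for DdCTD. Only 8 genes, singled out because they were few, were called in opposite directions: DDB_G0283639, mvd, gtaT, vps13D, gtaQ, cbfA, DDB_G0282701 and hbx2. The rise of cbfA with DdCTD may come from reads of the expressed domain, which was not tested.

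**Figure D3:**
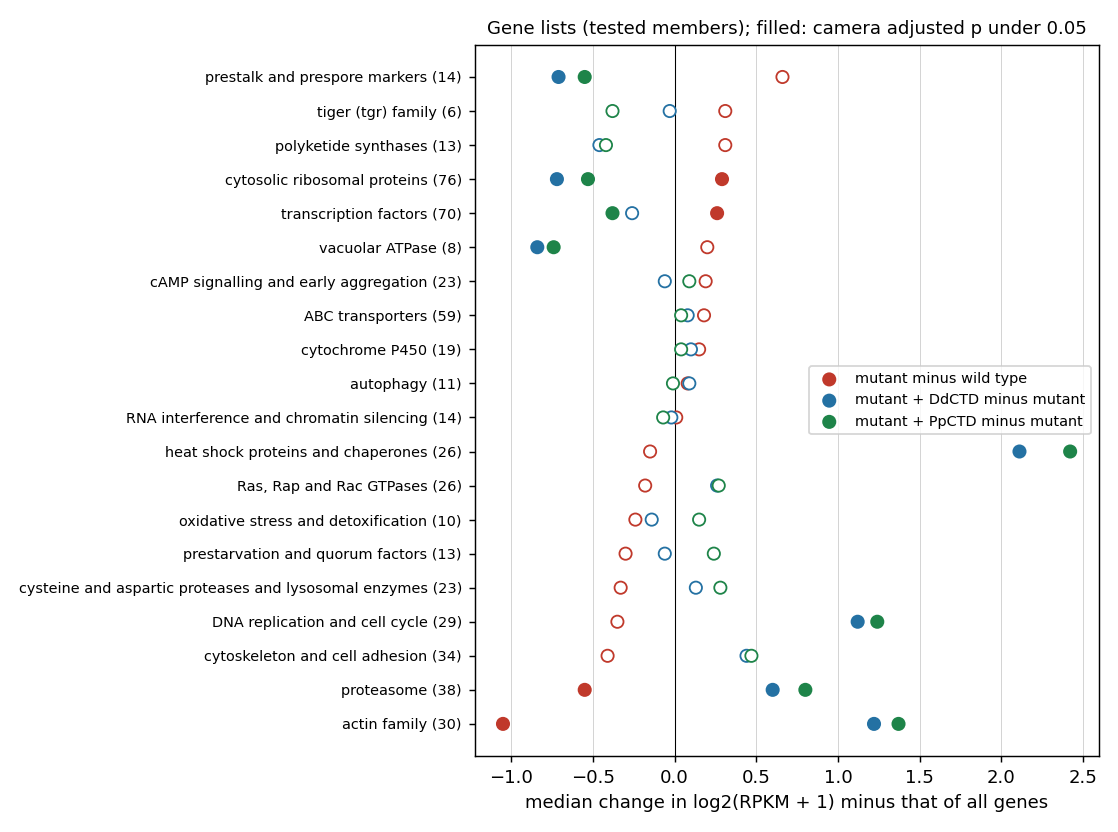
Median log2 fold change of the tested members of 20 gene lists minus the median of all genes, with the number of members in brackets, for mutant minus wild type and for each domain minus mutant; filled points had a camera adjusted p under 0.05 with the preset correlation. After quantile normalization the filled ribosomal protein points of both domains changed sign, as did open points of the prestarvation and cytochrome P450 lists with DdCTD. The cAMP points of both domains came to 0.00 there. With median-ratio scaling the ribosomal protein points kept their sign (-0.76 and -0.55). Open points of the RNA interference and tgr lists with DdCTD and of autophagy with PpCTD changed sign with that scaling.

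The comparison of each domain group with wild type asked what remained different. With DdCTD, the ponticulin-like genes ponC1 (0.678 ± 0.372 to 93.1 ± 24.6 RPKM), ponC2, ponC5 and ponC4 rose above wild type by 5.80, 5.70, 5.13 and 5.09, and hspG6 rose from 2.27 ± 0.705 to 115 ± 14.4 (SD, n = 3). abpF was lower by a log2 change of -5.48 and cxgS by -4.40. cmbB fell from 230.0 ± 155 to 20.4 ± 12.2, cprF from 661 ± 674 to 56.0 ± 9.45, with a wild-type spread above its mean, and srsA (DDB0237692) from 1038 ± 249.9 to 147 ± 55.6. DDB_G0289411 and DDB_G0284763 rose by 7.51 and 6.78, and DDB_G0271770 and DDB_G0290993 fell (-4.13 and -3.83). Limma called 4865 genes (54.9%), 3961 up and 904 down. The share up was 81.4%, against 47.2% after quantile normalization and 51% with median-ratio scaling, which moved the all-gene median of 0.29 by -0.33 and -0.27. The largest adjusted p among the 10 genes with descriptive symbols chosen by size was 0.00595 (cprF).

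With PpCTD, hspG6 rose above wild type to 114 ± 55.7 RPKM, hspG9 from 2.40 ± 0.785 to 74.4 ± 37.9, hspG5 from 0.617 ± 0.211 to 31.4 ± 18.5, hspG12, a gene in the chromosome 2 run, from 2.66 ± 2.56 to 61.6 ± 31.4, and lmcB from 71.1 ± 7.76 to 1466 ± 125 (SD, n = 3). abpF stayed at 0.467 ± 0.0285, a log2 change of -6.03. cprF, symA and srsA (DDB0237692) were lower by -2.82, -2.62 and -2.51. p80 was lower by -2.51, from 1128 ± 127 to 329 ± 402 (limma adjusted p = 0.012), and without PpCTD replicate 2 this was no longer called (-2.01, adjusted p = 0.0547). DDB_G0272030 and DDB_G0289411 rose by 5.93 and 5.27, and DDB_G0271770 and DDB_G0291344 fell (-4.43 and -3.92). Limma called 3557 genes (40.2%), 2652 up and 905 down. The share up was 74.6%, against 47.1% after quantile normalization and 52.7% with median-ratio scaling, which moved the all-gene median of 0.18 by -0.21 and -0.16. Of the 10 genes chosen by size in this way, cprF had the largest adjusted p (0.0134).

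DNA replication genes stood above wild type in both groups, thyA at 259.5 ± 74.3 and 252 ± 63.4 RPKM against 21.2 ± 3.03, and polA1 at 21.6 ± 1.70 and 22.0 ± 8.06 against 5.57 ± 0.809 (SD, n = 3). With DdCTD 26 of 29 rose and 0 fell, also when adjusted over the list alone (15 and 2 after quantile normalization, 17 and 1 with median-ratio scaling; relative median 0.62; camera adjusted p = 0.000845; adjusted p = 0.978 with an estimated correlation). With PpCTD 25 rose and 0 fell (26 and 0 adjusted over the list alone; 16 and 1 after quantile normalization, 18 and 0 with median-ratio scaling; relative median 0.75; camera adjusted p = 8.91e-06; adjusted p = 0.959 with an estimated correlation). Heat shock and chaperone genes rose in 17 and fell in 2 of 26 cases with DdCTD (17 and 3 adjusted over the list alone; relative median 1.37; camera adjusted p = 0.0377; adjusted p = 0.978 with an estimated correlation), a call lost without DdCTD replicate 3 (adjusted p = 0.0601), with no filter (0.0637) and with a replicate block (0.0667). With PpCTD 15 rose and 3 fell (16 and 3 adjusted over the list alone; relative median 1.17; camera adjusted p = 0.00227; adjusted p = 0.959 with an estimated correlation). Vacuolar ATPase genes lay below wild type, led by vatB, which is in the chromosome 2 run. With DdCTD 6 of 8 fell (7 adjusted over the list alone; 3 after quantile normalization, 8 with median-ratio scaling; relative median -0.66; camera adjusted p = 1.06e-05; adjusted p = 0.765 with an estimated correlation; 0.0761 after quantile normalization). With PpCTD 4 fell (7 adjusted over the list alone; 2 after quantile normalization, 8 with median-ratio scaling; relative median -0.52; camera adjusted p = 5.72e-05; adjusted p = 0.959 with an estimated correlation). Ribosomal protein genes fell in 42 and rose in 1 of 76 cases with DdCTD (also when adjusted over the list alone; camera adjusted p = 2.05e-21; adjusted p = 0.765 with an estimated correlation) and fell in 19 and rose in 2 with PpCTD (19 and 1 adjusted over the list alone; camera adjusted p = 1.57e-09; adjusted p = 0.959 with an estimated correlation). Their relative medians of -0.51 and -0.29 flipped to 0.05 and 0.04 after quantile normalization, where 18 fell and 19 rose with DdCTD, 16 fell and 13 rose with PpCTD, and both calls were lost. With median-ratio scaling 68 and 34 fell. Oxidative stress genes were called with DdCTD (1 rose and 3 fell of 10, 0 and 2 adjusted over the list alone; relative median -0.32; camera adjusted p = 0.0416; adjusted p = 0.846 with an estimated correlation), with sodE at 46.1 ± 6.14 against 118 ± 32.6. That call was lost without wild-type replicate 2 (adjusted p = 0.112), after quantile normalization (0.445) and with no filter (0.0977). Before the all-gene median was subtracted, the list median was -0.03 in the main fit and 0.03 with no filter. After quantile normalization 0 of these genes rose and 3 fell, and with median-ratio scaling 0 rose and 6 fell.

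**Figure D4:**
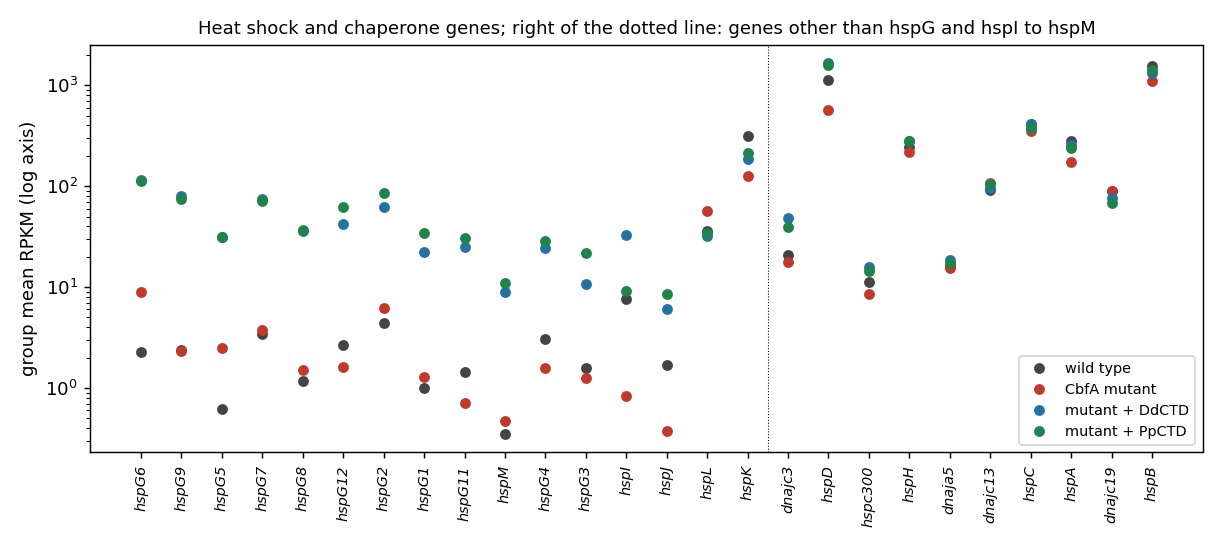
Mean RPKM (log axis) of the 26 tested heat shock and chaperone genes in the 4 groups (n = 3 libraries each). Left of the dotted line, the means with a domain lie far above wild type and mutant for most of the small heat shock genes, hspG6 at 115 and 114 against 2.27 and 8.96, but not for hspL and hspK or, with PpCTD, hspI; to the right, hspA, hspB and hspC differ far less.

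The direct comparison asked where the domain groups differ from each other. The labels do not say how strongly each domain was expressed or whether separate clones were used. A difference between the domains therefore cannot be told apart from a difference in their expression or between the strains carrying them. The gene cbfA was lower with PpCTD (-2.96, limma adjusted p = 1.84e-08), with a rise of 1.45 from the mutant with DdCTD and a change of -1.50 with PpCTD. Reads of the expressed D. discoideum domain may count on cbfA, which was not tested, so this difference need not be a response to the domains. ponC2 stood at 24.6 ± 14.6 RPKM with PpCTD and 107 ± 27.1 with DdCTD, and comH at 7.54 ± 5.001 and 36.0 ± 11.4 (SD, n = 3). ponC1 (-2.17) and ponC5 (-2.11) were lower too, but neither was called without DdCTD replicate 2 (-2.09 and -1.96, adjusted p = 0.104 and 0.105). CYP521A1 (8.48 ± 0.561 against 2.12 ± 0.537) and fscJ (14.6 ± 1.20 against 4.67 ± 1.99) were higher with PpCTD. So were ctnC (2.09), CYP513C1 (1.91) and cbpE (1.41), whose calls were lost without PpCTD replicate 3 (2.06 and 1.75, adjusted p = 0.0623 and 0.103) and without DdCTD replicate 2 (1.36, adjusted p = 0.122). DDB_G0283639 and DDB_G0274971 were higher by 2.55 and 2.52, and DDB_G0284763 and DDB_G0277489, the latter in the chromosome 2 run, were lower (-3.78 and -3.71). The transcription factor genes gtaT (79.1 ± 17.0 against 185 ± 9.10), gtaQ (18.1 ± 0.721 against 49.5 ± 7.52) and hbx2 (5.99 ± 0.650 against 14.7 ± 2.21) were lower with PpCTD, as was abcG12 (84.0 ± 15.8 against 244 ± 40.8). Limma called 445 genes (5.0%), 126 up and 319 down, or 28.3% up, against 50.5% after quantile normalization and 50.6% with median-ratio scaling, which both moved the all-gene median of -0.11 by 0.11. The count was 221 without DdCTD replicate 2, 268 without DdCTD replicate 3 and 216 without PpCTD replicate 3. By the fitted changes from the mutant, whether called or not, the DdCTD change was the larger in 278 of the 445 genes, the PpCTD change in 72, and the signs were opposite in 95.

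Transcription factor genes were lower with PpCTD as a list, 11 down and 1 up of 70 (23 and 3 adjusted over the list alone; relative median -0.15; camera adjusted p = 0.000186; adjusted p = 0.66 with an estimated correlation). Of the 6 tgr genes 1, tgrB1, was lower (3 adjusted over the list alone; relative median -0.32; camera adjusted p = 0.0423; adjusted p = 0.639 with an estimated correlation), a call lost without DdCTD replicate 1 (adjusted p = 0.0924), with a replicate block (0.0599) and with no filter (0.694). Prestarvation factors (1 up, ctnC, and 0 down of 13, 2 and 0 adjusted over the list alone; relative median 0.30; camera adjusted p = 0.001) had an adjusted p = 0.0864 with an estimated correlation and 0.0554 after quantile normalization. Prestalk and prespore markers (2 up, 0 down of 14, also when adjusted over the list alone; relative median 0.22; camera adjusted p = 0.0247; adjusted p = 0.639 with an estimated correlation) were not called without DdCTD replicate 2 (adjusted p = 0.0814) or with no filter (0.125). Cytochrome P450 genes numbered 2 up and 0 down of 19 (2 and 1 adjusted over the list alone; relative median 0.11; camera adjusted p = 0.0118; adjusted p = 0.708 with an estimated correlation), a call lost with no filter (0.371). Before the all-gene median was subtracted, their median was 0 in the main fit and -0.01 with no filter. Proteasome genes numbered 0 up and 0 down of 38 by limma, also when adjusted over the list alone, at an unadjusted p under 0.05 and by limma voom on the reads (relative median 0.17; camera adjusted p = 0.000807; adjusted p = 0.708 with an estimated correlation). Ribosomal protein genes numbered 2 up and 0 down of 76 (0 and 0 adjusted over the list alone; relative median 0.21, which flipped to -0.01 after quantile normalization; camera adjusted p = 3.82e-17; adjusted p = 0.639 with an estimated correlation). This camera call was lost after quantile normalization (adjusted p = 0.925). With median-ratio scaling the relative median was 0.22.

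Of the 120 list tests 35 were called by camera, and 0 held with an estimated correlation, where 2 tests had an unadjusted p under 0.05. The signs of median, mean and camera direction differed in 30 tests, 1 of them called: the cytochrome P450 list between domains, with a median of 0.00 and a mean of 0.18. Fry, which tests whether members move on balance one way whatever other genes do, called 75 of the 120 tests and gave for mutant against wild type an adjusted p of 0.00337 for the proteasome, 0.00301 for actin, 0.011 for ribosomal proteins and 0.00337 for transcription factors. The remaining lists were not called in any comparison in the main fit. After quantile normalization camera called cytoskeleton and adhesion genes for both domains against mutant (adjusted p = 0.0247 and 0.0138) and for PpCTD against wild type (0.0256). With no filter it called them for mutant against wild type and PpCTD against mutant. It then also called Ras, Rap and Rac genes for both domains against mutant and proteases for PpCTD against mutant. Medians of the remaining lists relative to all genes, for mutant minus wild type and for DdCTD and PpCTD minus mutant, were as follows. cAMP signalling and early aggregation genes (23 tested) had 0.19, -0.06 and 0.09, and those for RNA interference and chromatin silencing (14) had 0.01, -0.02 and -0.07. Cysteine and aspartic protease and lysosomal genes (23) had -0.33, 0.13 and 0.28, and polyketide synthases (13) had 0.31, -0.46 and -0.42. ABC transporter genes (59) had 0.18, 0.08 and 0.04, and cytoskeleton and adhesion genes (34) had -0.41, 0.44 and 0.47. Ras, Rap and Rac genes (26) had -0.18, 0.26 and 0.27, and autophagy genes (11) had 0.08, 0.09 and -0.01. Of these, the DdCTD and PpCTD medians of the cAMP list (0.00 and 0.00 after quantile normalization), the RNA interference median with DdCTD (0.12 with median-ratio scaling) and the autophagy median with PpCTD (0.04 with median-ratio scaling) did not keep their sign. The hssA/2C/7E family had 1 gene among the models and 0 tested.

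A run of 240 neighbouring tested genes at the end of chromosome 2, from gxcBB to DDB_G0277785 in the gene order of dicty_2.7, was lower in all groups derived from the mutant. Its median relative to all genes was -0.75 for the mutant, -0.86 with DdCTD and -0.85 with PpCTD, each minus wild type. Limma called 176, 150 and 157 of the 240 genes lower. Relative to the mutant, the run had a median of -0.08 with either domain. Named genes inside it are thfA, DDB_G0277333, piaA, cotC, vatB, rps3a, cycD, stkA, atg3, gpbA, rps27, hspG12, gtaC and DDB_G0277489.

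**Figure D5:**
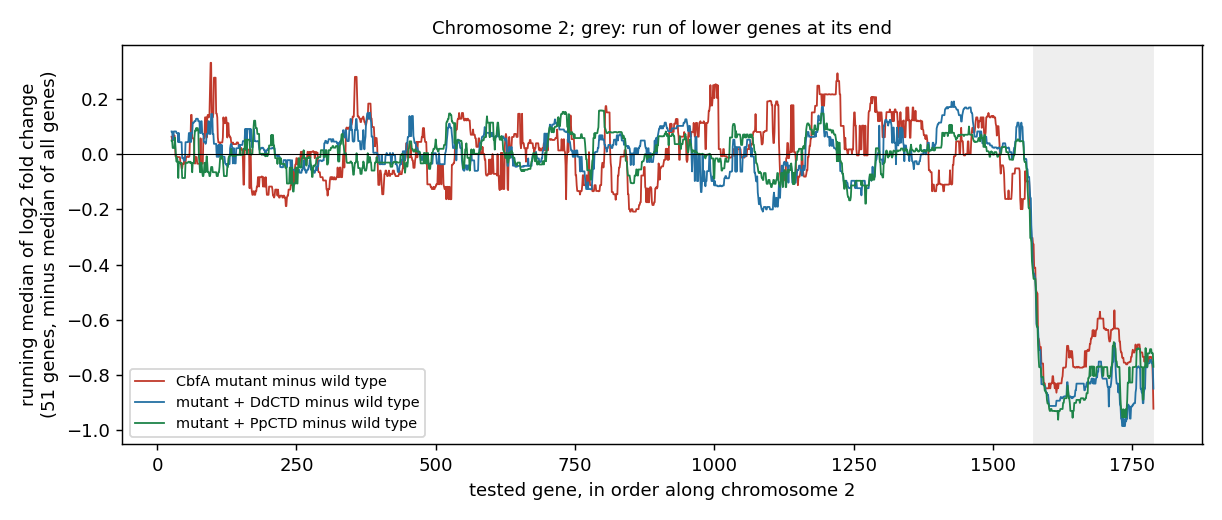
Running median over 51 tested genes (full windows only) of the log2 fold change against wild type, minus the median of all genes, along chromosome 2, for the mutant and for the mutant with DdCTD or PpCTD; the grey area is the run of 240 genes. All 3 lines leave the level near 0 at the start of the run and stay low to its end.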

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

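The tests of the run's scaling, of the domain acting on it and of its expression classes on reads, of the share of rises under median-ratio scaling, and of chaperones and summed hspG reads were chosen only after the results were seen.

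Genes that differed between the domain groups were singled out by the direct test of PpCTD against DdCTD, limma at an adjusted p under 0.05. The limit given above on strains and expression of the domains applies here too. It called 445 genes, 221 without DdCTD replicate 2, 268 without DdCTD replicate 3 and 216 without PpCTD replicate 3. Higher with PpCTD by log2 changes were CYP521A1 (1.61) and fscJ (1.52), DDB_G0283639 (2.55) and DDB_G0274971 (2.52). ctnC (2.09), CYP513C1 (1.91) and cbpE (1.41) were higher too, and without PpCTD replicate 3 for ctnC (2.06, adjusted p = 0.0623) and CYP513C1 (1.75, adjusted p = 0.103), or DdCTD replicate 2 for cbpE (1.36, adjusted p = 0.122), they were not called. Lower with PpCTD were cbfA (-2.96), ponC2 (-2.25) and comH (-2.22), DDB_G0284763 (-3.78) and, inside the chromosome 2 run, DDB_G0277489 (-3.71). For cbfA, reads of the expressed D. discoideum domain may count on the gene, which was not tested. ponC1 (-2.17) and ponC5 (-2.11) were lower as well, with reads uncertain between copies, and were not called without DdCTD replicate 2 (-2.09 and -1.96, adjusted p = 0.104 and 0.105).

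The run of 240 lower genes at the end of chromosome 2 was searched for with a running median over 51 genes along 8722 ordered genes, which found 1 lower and 0 higher runs past 0.4. In the run 79.6% of the genes lay below the all-gene median in mutant, DdCTD and PpCTD, each against wild type, against 20.6% of other genes, and the lowest of 708 other windows of 240 genes had medians of -0.12, -0.09 and -0.06. The run was chosen by these same values, so these figures describe it and do not test it. After quantile normalization the run's median, mutant minus wild type, was -0.69. Normalizing whole libraries shifts genes of like level wherever they lie, so this test could hardly have come out otherwise. The DdCTD median of the run relative to the mutant was -0.08, where 2376 other genes that had fallen had 0.75. The run was chosen for lying below wild type in mutant, DdCTD and PpCTD alike, so a stretch restored by a domain would not have been found. That median therefore decides nothing about the domain acting on the run. A copy number difference should shift genes alike whatever their expression. Class medians of -0.62, -0.93 and -1.06 from low to high differed by 0.44 (interval 0.30 to 0.63), past the bound of 0.3 set beforehand. That counts against a uniform shift in these values, but log2(RPKM + 1) compresses the low class, whose median was 3.08 RPKM. On reads the class medians were -0.73, -0.99 and -1.1 and differed by 0.37 (0.21 to 0.54), which spans the bound. The largest difference between class medians also grows with noise. A copy number difference between wild-type cells and mutant lineage is left as a possible explanation not settled here.

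More genes were higher than lower with a domain, with an all-gene median of 0.27 for DdCTD minus mutant. Median-ratio scaling gave 50.2% rises, but it centres the fold changes and so decides nothing about scaling by the library total. With the 100 most abundant genes left out of the totals the median was 0.13, between the bounds set beforehand, and 0.06 with PpCTD; these genes took 35.8% to 37.6% of the reads in mutant libraries and 28.7% to 30.3% with DdCTD. A few abundant genes may therefore account for part of the shift. A rise in RNA per cell was not tested by any measure and stays open.

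Small heat shock genes lay above wild type with both domains, hspG6 and hspG9 among them. The 16 small genes, a class set after values were seen, had medians of 3.52 and 3.77 (DdCTD and PpCTD), and 14 and 13 rose. A general heat shock response raising the other chaperones by over 1 was argued against by medians of 0.11 and 0.13 for the 10 other genes of the list (0.05 and 0.08 for 9 without hspc300, a SCAR complex gene); 3 rose and 1 fell with DdCTD and 2 rose and 2 fell with PpCTD, with hspD at 0.54 and 0.49 and dnajc3 at 1.15 and 0.87, so a response of some chaperones stays open. Reads moved between hspG copies with no rise in their total were argued against by sums over 12 hspG models. These were 13.9 ± 6.16 RPM in wild type, 18.8 ± 0.310 in the mutant, 317 ± 70.6 and 355 ± 183 with the domains (SD, n = 3), 22.8 times and 25.6 times wild type. Reads of a few risen copies spread over similar ones would raise the sums too, so how many hspG genes rose was not settled. Carrying a construct or its selection could act alike with either domain (median PpCTD minus DdCTD of 0.10), and no library with a construct and no domain was analysed, so it cannot be told apart from an action of the domain, itself untested.

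Other splits of the libraries were counted for each result. The 10 splits of 6 libraries are too few for a share under 0.05: 1 split, the real one, gave as many genes in each comparison, with 4844, 5757, 5449, 4865, 3557 and 445 genes, and the highest other gave 0, or 1 for PpCTD against wild type. For genes reversed by DdCTD (3401), by PpCTD (3575) and the overlap of the domains (4816), 1 of 100 drawn splits of 9 libraries gave as many, the real one, and the highest others gave 2760, 3233 and 4791. Of the 99 others 95, 95 and 97 divided the mutant libraries (highest 2215, 1263 and 25) and 4, 4 and 2 kept them together. Dividing the mutant libraries puts their difference from the others inside groups, which lowers the calls. The draws therefore show mainly that the mutant libraries are alike, and do not exclude chance for these counts. Nor can they exclude differences between cultures, which the labels do not describe. With the mutant group fixed there are 10 splits, too few for a share under 0.05; the real one gave the most and the highest others 2809, 3233 and 4810.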

How the results depend on the processing

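The voom fits and the fits without the chromosome 2 run were chosen after results were seen, and the other alternatives beforehand; DESeq2 tests and edgeR with RLE size factors were not run, as the deposited unit is RPKM; they were not run on the recovered reads either, to which limma voom alone was applied. Requiring at least a doubling or halving left 1480 genes for mutant against wild type, 2258 and 2068 for DdCTD and PpCTD against mutant, 1212 and 932 against wild type, 165 for PpCTD against DdCTD, 1005 and 1050 reversed and 1804 shared. Without 1 library the counts ranged from 4143 to 4787 for mutant against wild type, 5201 to 5424 and 4857 to 5231 for DdCTD and PpCTD against mutant, 3763 to 5115 and 2445 to 3949 against wild type, 216 to 446 for PpCTD against DdCTD, 2886 to 3581 and 3038 to 3750 reversed, and 4330 to 4677 shared. For PpCTD against DdCTD, 221 genes were called without DdCTD replicate 2, 268 without DdCTD replicate 3 and 216 without PpCTD replicate 3, and the cause was not tested. Quantile normalization, no filter, pseudocount 0.1, only the libraries compared, voom, and fits without the run moved none of these counts by over 1.5 times. The genes behind the counts changed more. For DdCTD against wild type, quantile normalization kept 2576 of the 4865 calls and voom 2881. Lost rises numbered 2232 and 1982 in that comparison, and 1522 and 1238 for DdCTD against mutant. Replicate numbers did not pair the libraries, as same-number libraries had r of -0.23 to 0.38 across genes after group means were removed and 5 of 12 libraries correlated best with their own number. A replicate block gave 4916, 5790, 5531, 4960.0, 3637, 462, 3457, 3643 and 4890.0 genes in the order mutant against wild type, DdCTD and PpCTD against mutant and then against wild type, PpCTD against DdCTD, reversed by each, and shared. Of 122 values of genes named by size, leave-one-out weakened 8, quantile normalization 2 (agnC, each domain against wild type), pseudocount 0.1 weakened 1 (ponC1, PpCTD against DdCTD), and voom, no filter and the block 0. Of 456 values of list members, leave-one-out weakened 29, voom 22, quantile normalization 26, no filter 6, pseudocount 3 and the block 4. Quantile normalization reversed 5, tgrB1 for PpCTD minus mutant (-0.11) and, for DdCTD minus wild type, pks18 (-0.06), pks19 (-0.08), pks17 (-0.12) and pks3 (-0.14), all uncalled there. Of 35 called lists, an estimated correlation kept 0, quantile normalization lost 10, no filter 5 (heat shock and oxidative stress for DdCTD against wild type; prestalk and prespore, cytochrome P450 and tgr for PpCTD against DdCTD), leave-one-out 4, the block 2 (heat shock and tgr in those comparisons) and pseudocount 0.1 lost 0. Of 85 uncalled lists no filter called 10, quantile normalization 4, and the pseudocount and block 1 each.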

Other observations

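Neighbouring genes moved together in the mutant at a place singled out because of its size. Between sgmD and DDB_G0268334, which stood at 37.1 ± 3.32 and 10.7 ± 1.16 RPKM in wild type and 27.3 ± 3.74 and 7.32 ± 0.583 in the mutant, lie 3 genes of higher expression in the mutant. DDB_G0268332 went from 53.3 ± 9.21 to 1667 ± 555, DDB_G0267726 from 26.3 ± 5.45 to 2333 ± 59.0, and DDB_G0267728 from 102 ± 29.4 to 5378 ± 1626 (SD, n = 3). With DdCTD they stood at 23.3 ± 8.27, 126 ± 13.4 and 91.4 ± 34.1, and with PpCTD at 63.6 ± 19.4, 279.7 ± 58.6 and 216 ± 45.4. A few genes further, DDB_G0267734 went the other way, from 499 ± 88.3 to 42.9 ± 15.03, and returned to 646 ± 86.3 and 502 ± 80.1. These places were found by looking at the genes of largest change, no test was chosen beforehand, and limma gave adjusted p of 2.16e-07, 3.78e-10, 6.32e-08 and 2.16e-07 for these 4 genes in mutant against wild type.

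The adjacent genes abpF and DDB_G0291344 were near lost in all groups derived from the mutant. DDB_G0291344 had 34.4 ± 1.99 RPKM in wild type and 0.709 ± 0.360, 2.73 ± 0.336 and 1.36 ± 0.477 in mutant, DdCTD and PpCTD (SD, n = 3). The genes beside them were far less affected, DDB_G0291342 at 7.56 ± 1.92 and 6.07 ± 0.274 and mleuS at 15.7 ± 1.40 and 10.5 ± 0.169 in wild type and mutant. No cause was tested.

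Against the mutant, 8 genes were called in opposite directions for the domains. Among them cbfA may carry reads of the expressed D. discoideum domain, which was not tested. gtaT stood at 99.6 ± 5.49 RPKM in the mutant, 185 ± 9.10 with DdCTD and 79.1 ± 17.0 with PpCTD, gtaQ at 24.95 ± 2.60, 49.5 ± 7.52 and 18.1 ± 0.721, and mvd at 111 ± 2.37, 94.0 ± 6.71 and 145 ± 3.81 (SD, n = 3). DDB_G0283639 went from 3.79 ± 1.26 to 0.680 ± 0.570 with DdCTD and to 8.66 ± 2.20 with PpCTD, against 11.5 ± 5.51 in wild type. DDB_G0282701 went from 30.3 ± 2.89 to 58.8 ± 7.47 and 17.2 ± 3.74.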
